A study of Mus musculus with 9 samples.

How the data were processed

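The series measured poly(A) RNA of mouse intestinal epithelium by paired-end sequencing, per the labels' protocols: 3 control libraries and 2 sets of 3 mutant libraries, each with 1 library at day 8, day 9 and day 10. The values the authors deposited are FPKM, fragments scaled to transcript length and library size, for 24930 gene symbols. The unit was read from the values, since the sources used here do not name it. The values are not whole, the column sums differ, the smallest values shrink with transcript length (1800 genes with a transcript of at least 2000 bases were used), and the median ratio to the geometric mean over 15138 genes is 1.00276 in every library. That last point is what scaling by median-of-ratios size factors gives. The submitters' processing notes name kallisto 0.46.1, DESeq2 1.40.1 and the genome build mm9, without saying which tool did which step. The annotation and any filter are not given in the sources used here. The reference used here was of another build (GENCODE M21), so no coordinates are given, and it served only for gene names and for the identity of transcripts, which was found with blastn.

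Samples were grouped by title. Titles and library names disagree on which mutant set carries the Cdx2 allele, so the sets are called A (titled with the β-catenin allele alone) and B (titled with both). Replicates 1, 2 and 3 are days 8, 9 and 10. The labels do not say that libraries came from separate animals, though each library name has its own number, so p-values measure the spread between these libraries.

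The design had been written for read counts, with a rule for normalized values. The file held FPKM, so that rule was used: limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), for the 12097 genes with at least 1 FPKM in at least 3 libraries. A model of group means was fitted to all 9 libraries with a shared, moderated spread (trend and robust options), and p-values were adjusted by Benjamini and Hochberg's method with a threshold of 0.05. A log2 fold change with this pseudocount understates the change of low genes. The contrasts were the mean of both sets against control, each set against control, and set B minus set A, and a further model held a slope over days. On simulated data for both sets against control (10 simulations over 12097 genes, 200 of them changed), 89% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were found, and 4.84% of the calls were false. The simulated noise was drawn independently for each gene and library, with no outlying library, so these shares may not hold for the real libraries.

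Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) with adjustment over 108 tests of 27 lists and 4 contrasts. Limma's fry, a rotation test, was planned and run beside it. It asks whether a list's own genes differ, not whether they differ more than other genes. Its values with all 9 libraries are not given here. B and plasma cell, enteric glia and mitochondrial lists had fewer than 3 tested members and were not tested, and the sex-linked list served as a check of the libraries. A single comparison of 1 gene used an exact permutation test. The choices of test, gene lists and named genes were made before the data were examined. The text names Ctnnb1, Cdx2, Axin2, Lgr5, Olfm4, Ly6a, Clu and Lyz1 in any case. It also names the 6 largest rises and 6 largest falls that passed, with a mean log2 value of at least 3, no overlap between the groups and a proper symbol, and up to 3 passing members of each list. Where nothing passed, it names the 5 genes with the smallest p. Other genes were chosen after their values were seen: Xist and the Y-linked genes, Rpl34-ps1, Tgtp1, Mir7036b, Pcsk6, Nkd1, Lcn2, Trpm5, Gm12191, Pla2g2a, Notum, Reg3b, Cd3e, Col3a1, Hbb-bs, Anxa3, Tnfrsf19, Fstl1, Lct and Cyp3a11.

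The step between low values sets the precision of low genes: at 1 FPKM a transcript of 1 kilobase rests on 16.8 to 19.1 fragments. The alternatives tried were another pseudocount (0.1), no filter, a stricter filter (5 FPKM), rescaling to equal totals, library weights, the day as a block, a fold change limit, fits to the compared groups alone, and leaving out each library. No column was left out.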

Results

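RNA was measured in crypt epithelium of the mouse intestine 8, 9 and 10 days after a mutant allele of Ctnnb1, the gene for β-catenin, was induced. The table held 24930 gene symbols in 9 libraries: 3 control libraries and 2 sets of 3 mutant libraries, with 1 library of each group per day. The titles give mutant set A as heterozygous for the β-catenin allele and mutant set B as heterozygous for both that allele and Cdx2, whereas the library names carry CDX2HET and EXON3 for set A and EXON3 alone for set B. The labels therefore conflict on which set carries the Cdx2 allele, and the sets keep the neutral names A and B here. Summed FPKM ran from 624923 to 755802 per library. The steps between low values put 1 FPKM at 16.8 to 19.1 fragments per kilobase of transcript. On the first principal component (43.5% of the variance) the controls lay at −21.6 to −22.7 and 5 mutant libraries at 2.57 to 30, while the day-9 library of set B lay at −19.1. That library also had Xist at 0.1 FPKM and 4 Y-linked genes at a sum of 41.7, against 27 to 39.4 and at most 0.047 in the other 8, the pattern of a male beside 8 females. Group values are means ± SD with n = 3 for control and each set and n = 6 for both sets together, and log2 fold changes are on the log2(FPKM + 1) scale with their standard error.

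The genes named in the labels were read first. Ctnnb1 averaged 195 ± 10.5 FPKM in control, 222 ± 14.6 in set A and 232 ± 8.06 in set B. Its difference between both sets and control was 0.22 ± 0.07 on the log2 scale, which did not pass the test over all genes (adjusted p = 0.126), although all 6 mutant libraries lay above every control library (two-sided exact permutation p = 0.0119, the smallest that 3 against 6 allows). A gene-level value does not show which exons a transcript holds. Cdx2, a homeobox regulator of intestinal identity, averaged 120 ± 16.6 FPKM in control, 134 ± 9.28 in set A and 187 ± 8.6 in set B. It rose in set B against control by 0.64 ± 0.105 (adjusted p = 0.0442), a call kept in 2 of 9 fits that each left out a library. Set B lay above set A by 0.48 ± 0.105, which did not pass over all genes (adjusted p = 0.948), and its 3 libraries were all above the 3 of set A (two-sided exact permutation p = 0.1, the smallest possible). Set A was not below control either (ratio 1.11, two-sided exact permutation p = 0.3), so neither set had the lower Cdx2 level that loss of 1 copy could bring, and the level does not settle which set carries the allele. Directions between the sets below are given for the libraries as titled A and B.

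**Figure D1:**
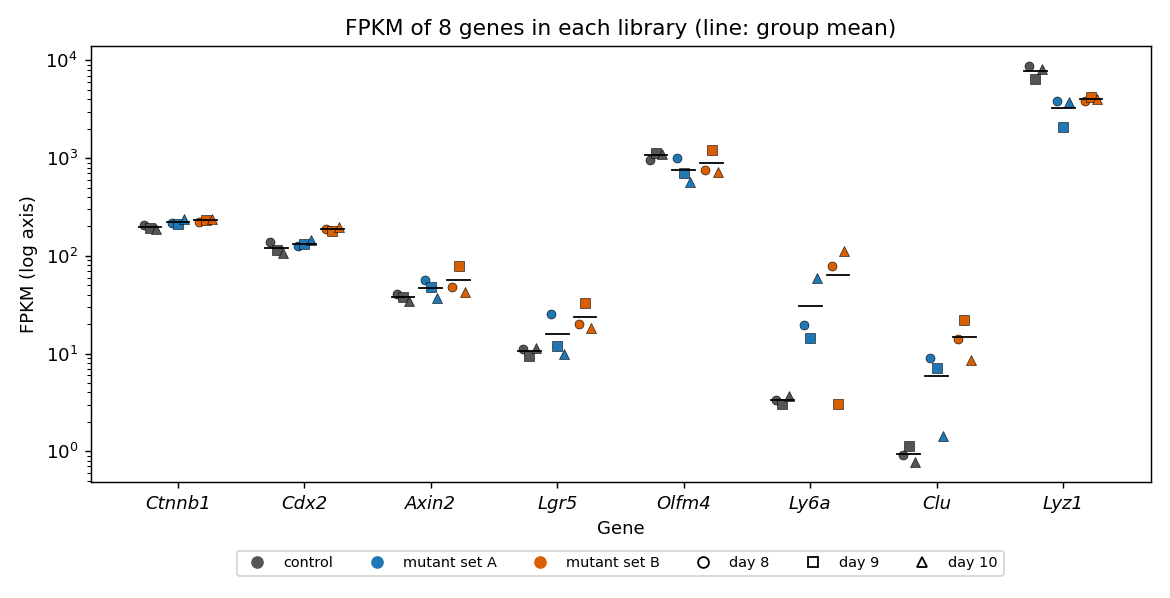
FPKM (log axis) of 8 genes chosen before the data were examined, 1 point per library, with colour for the group, shape for the day and a line at each group mean. Lyz1 lay between 2090 and 4250 FPKM in the mutant libraries and between 6450 and 8820 in control, and Ly6a was at 3.06 in the day-9 library of set B against 14.5 to 111 in the other mutant libraries.

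Comparing both mutant sets with control asks how the mutant libraries differed from control after induction. An inherited difference between these groups, raised below for Rpl34, could not be told apart from the mutant allele. Several genes of the Paneth cell, the antimicrobial cell at the crypt base, fell. Ang4, which encodes an antimicrobial angiogenin, averaged 4150 ± 2720 FPKM in control and 737 ± 241 in the mutants (log2 −2.38 ± 0.42, adjusted p = 0.0473), and the defensin genes Defa6 and Defa29 fell by 1.69 and 1.70 on the log2 scale. Several replication genes fell by smaller amounts, with Uhrf1, a factor in the copying of DNA methylation, at 38.5 ± 3.66 FPKM in control and 27.3 ± 1.5 in the mutants (log2 −0.47 ± 0.07, adjusted p = 0.032). The largest rises among the genes named by rule were Akr1b8, an aldo-keto reductase, from 6.79 ± 1.59 to 28.1 ± 6.75 FPKM (log2 1.89 ± 0.18, adjusted p = 0.00655), and Sprr2a3, a small proline-rich protein gene, from 33.5 ± 8.51 to 120 ± 36.4 (1.78 ± 0.21, adjusted p = 0.0134), a member of a family of close paralogs, so its single value is uncertain. Pla2g5 rose from 25.4 ± 3.55 to 73.9 ± 9.12 FPKM, and Igfbp4, Ccdc3 and Gkn3 rose by 1.75, 1.35 and 1.17.

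In all, 140 of 12097 genes tested passed an adjusted p of 0.05 in limma, 62 higher and 78 lower in the mutants, and 2537 had an unadjusted p under 0.05 where chance alone gives 605. The count depended on single libraries. Without the day-9 library of set B, which stood apart from the other mutants, 994 genes passed (557 higher and 437 lower), and they held all 140. Leaving out another library gave 36, 18 or 17 genes without control replicate 1, 2 or 3, then 112, 69 and 55 without set A replicate 1, 2 or 3, and 43 and 51 without set B replicate 1 or 3. Of the 26 named genes that passed, Akr1b8, Pla2g5, Ccdc3, Rpl34 and Rpl30 passed whichever library was left out. With the libraries rescaled to equal totals 169 genes passed, 133 higher and 36 lower, so the balance of directions depends on the scaling.

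**Figure D2:**
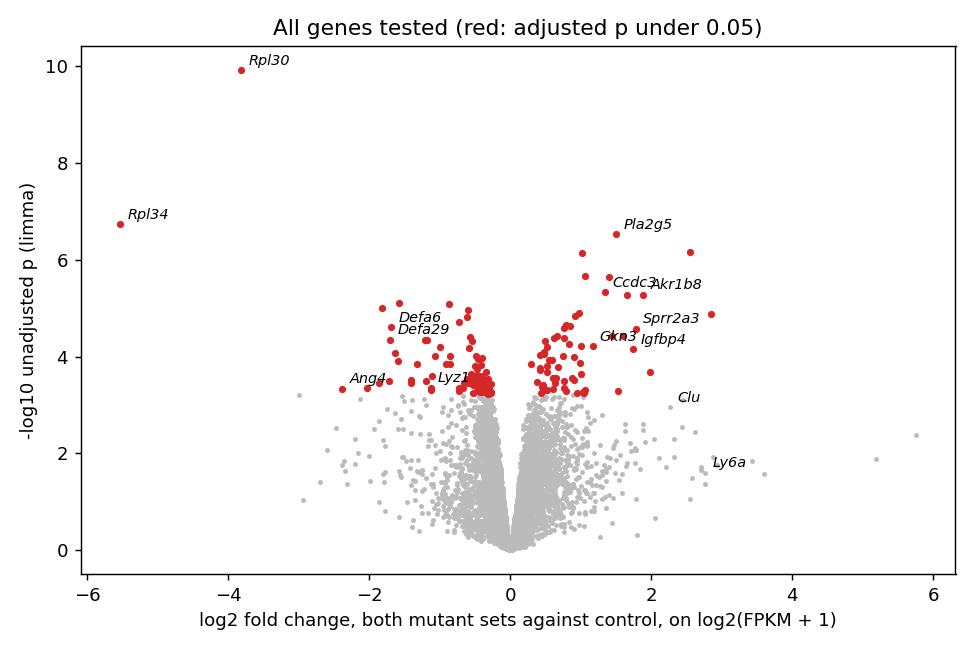
Log2 fold change of both mutant sets against control, on log2(FPKM + 1), for each of 12097 genes, against −log10 of the unadjusted limma p, with the 140 genes past the adjusted threshold in red. Rpl34 at −5.53 and Rpl30 at −3.82 were the largest falls among the named genes, while Ly6a at 2.77 and Clu at 2.26 did not pass.

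The Rpl34 and Rpl30 values need their copies beside them. Rpl34, a ribosomal protein gene, fell from 766 ± 267 to 15.7 ± 7.03 FPKM (log2 −5.53 ± 0.33, adjusted p = 0.00109), and Rpl30 fell from 380 ± 43.6 to 26.1 ± 3.82 (−3.82 ± 0.10, adjusted p = 1.42e-06). The pseudogene Rpl34-ps1, 99.4% identical to Rpl34 over 354 bases, was at 928 to 1130 FPKM in the mutants, and the gene model Gm12191, 99.7% identical to Rpl30 over 348 bases, was at 708 to 836. The sum of Rpl34 and Rpl34-ps1 was 937 ± 47.3 in control and 1070 ± 76 in the mutants, and that of Rpl30 and Gm12191 was 766 ± 75.2 and 811 ± 44.3. Neither fall was a fall of the summed copies, so the values of these genes are uncertain.

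**Figure D3:**
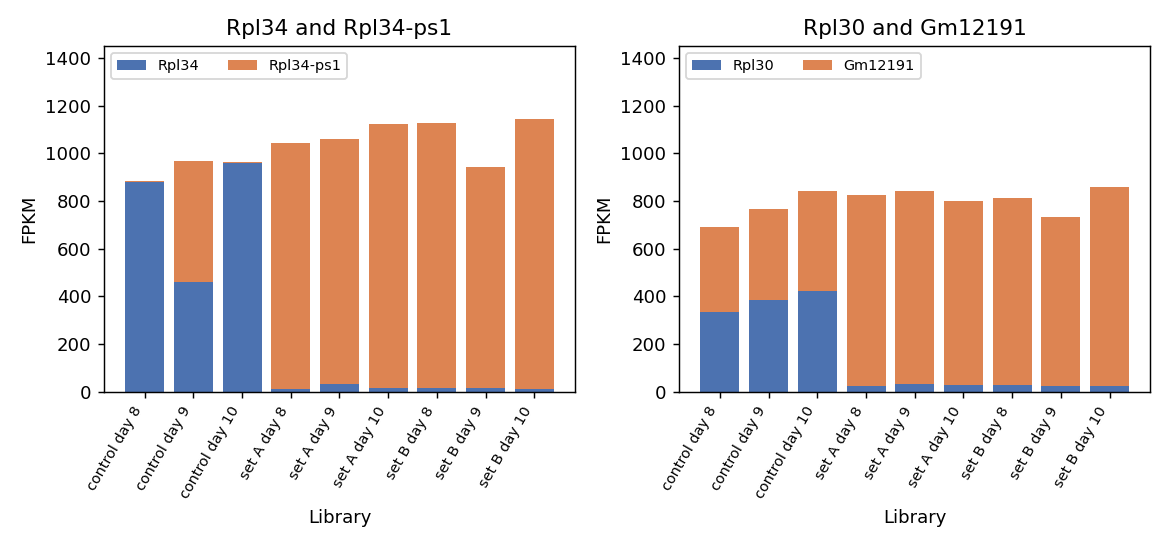
FPKM of Rpl34 and Rpl34-ps1 (left) and of Rpl30 and Gm12191 (right), stacked for each of the 9 libraries. The copy made up 97.2 to 98.9% of the Rpl34 sum and 96.2 to 97.5% of the Rpl30 sum in the mutants, and in control replicate 2 Rpl34-ps1 made up 52.3%.

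Of 31 gene lists fixed before the data were examined, 27 had at least 3 tested members and were tested in each of 4 contrasts by limma's camera. At a preset correlation of 0.01 between genes, 45 of these 108 tests passed. With a correlation estimated for each list none did, the smallest adjusted p being 0.323, so each list below is described by its members, and a list that passed at the preset correlation has its p from both settings. Among 17 Paneth cell markers 5 fell and none rose (13 lower and 1 higher adjusted over the list alone), with a median log2 fold change of −1.28 (adjusted p = 2.54e-08, and adjusted p = 0.501 with an estimated correlation). Defa30 and Defa24 fell by 1.59 and 1.41, Clps, the colipase gene, by 1.72 and Lyz1, the lysozyme gene, by 1.13 (adjusted p = 0.0456). Of the 17, 8 fell without the day-9 library of set B, but only 0 to 6 without any 1 of the other libraries, where Pla2g2a rose in 1 case. Ang4 was kept in 1 of the 9 fits that left out a library, Clps in 2, Lyz1 and Defa24 in 3 and Defa30 in 5. The defensin genes are near-identical paralogs, so single values are uncertain, but their summed FPKM was 94900 ± 24400 in control and 40100 ± 9470 in the mutants, without overlap. Pla2g2a, a phospholipase gene on the same list, went the other way: it was at 132, 93.7 and 8270 FPKM in the control libraries and at 2690 to 10200 in the mutants, and did not pass (adjusted p = 0.182). The highest control lay inside the mutant range, so this gene did not separate the groups. An inherited difference between the libraries was not tested as a cause.

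Among 23 S phase genes 7 fell, including Uhrf1, Cdc6 (log2 −0.44) and Mcm5 (−0.43), and 22 were lower adjusted over the list alone (median −0.36, adjusted p = 3.75e-16, and adjusted p = 0.323 with an estimated correlation). Cdc6 and Mcm5 encode parts of the replication licensing machinery. Of the 23, 16 fell without the day-9 library of set B, but only 0 to 2 without any 1 of the other libraries. Cdc6 and Mcm5 were kept in 1 of the 9 fits and Uhrf1 in 3. Among 23 G2/M genes Ttk, a spindle checkpoint kinase, was the 1 that fell, against 5 without the day-9 library of set B and 0 to 1 without any 1 other (Ttk −0.54 ± 0.07, adjusted p = 0.0167), and 18 were lower adjusted over the list alone (median −0.25, adjusted p = 1.66e-10, and adjusted p = 0.53 with an estimated correlation). All members of both lists had a negative fold change. None of 12 tuft cell markers passed, though all were negative (median −0.77, adjusted p = 0.000436, and adjusted p = 0.674 with an estimated correlation). Without the day-9 library of set B 3 of the 12 fell, and 12 were lower adjusted over the list alone in that fit. Without any 1 other library 0 fell over all genes. None of 11 T cell and intraepithelial lymphocyte markers passed either, and all were negative (median −0.67, adjusted p = 0.0112, and adjusted p = 0.765 with an estimated correlation). The lowest medians of both lists were in the day-10 mutant libraries. The T cell list median on log2(FPKM + 1) was 2.12 to 2.83 in control, 2.06, 2.51 and 0.92 at days 8, 9 and 10 of set A, and 1.65, 2.66 and 0.93 in set B, so both day-9 libraries lay inside the control range. The tuft cell list median was 1.97 to 2.53 in control, 2.06, 1.90 and 0.89 in set A, and 1.44, 2.37 and 1.07 in set B. Cd3e, a T cell receptor subunit, was at 2.19 to 3.17 FPKM in control, 1.92, 2.08 and 0.526 in set A, and 1.32, 2.39 and 0.306 in set B.

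Of 17 fetal and regenerative epithelium markers 5 rose and none fell (10 higher adjusted over the list alone), with a median of 0.49 (adjusted p = 3.95e-06, and adjusted p = 0.323 with an estimated correlation). They were Krt7, a keratin (0.49 ± 0.07, adjusted p = 0.0167), Plaur, the urokinase receptor (0.84 ± 0.11), Marcksl1 (0.99 ± 0.15), Anxa3 (0.95 ± 0.18) and Areg, an EGF receptor ligand (1.53 ± 0.27, adjusted p = 0.0487). Of the 17, 8 rose without the day-9 library of set B and 0 to 4 without any 1 other. Ly6a, which encodes the fetal marker Sca-1, averaged 3.38 ± 0.314 FPKM in control and 47.6 ± 42.4 in the mutants (2.77 ± 1.00, adjusted p = 0.176), and Clu, which marks regenerating crypts, averaged 0.942 ± 0.183 and 10.3 ± 7 (2.26 ± 0.46, adjusted p = 0.0626), so neither passed. On the list of 20 ligands from epithelium to stroma, Areg and Vegfa, an endothelial growth factor, rose (Vegfa by 0.88 ± 0.15, adjusted p = 0.0417), and the list as a whole did not pass (adjusted p = 0.217). Vegfa was kept in 1 and Areg in 2 of the 9 fits that left out a library.

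None of 20 WNT target genes passed over all genes, while 8 were higher and 2 lower adjusted over the list alone (median 0.40, adjusted p = 0.00414, and adjusted p = 0.674 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, averaged 37.7 ± 3.41 FPKM in control and 51.7 ± 14.4 in the mutants (0.41 ± 0.20, adjusted p = 0.284). Notum lay at 0.0802 to 0.22 FPKM in control, at 0.394 to 2.46 in 5 mutant libraries and at 12.5 in the day-9 library of set B. Without that library 5 members of the list rose and 1 fell, and 0 passed without any 1 other. Among 20 crypt base stem cell markers Igfbp4 was the 1 that rose, against 3 without the day-9 library of set B and 0 to 1 without any 1 other, and the list did not pass (median 0.12, adjusted p = 0.0565). Lgr5, a stem cell receptor, was 0.73 ± 0.30 higher (adjusted p = 0.213) and Olfm4 0.41 lower (log2 −0.41 ± 0.21, adjusted p = 0.309), neither passing.

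None of 27 interferon response genes passed, although all 27 had a positive fold change (median 0.57, adjusted p = 2.89e-06, and adjusted p = 0.674 with an estimated correlation). None of 17 epithelial antimicrobial and inflammatory genes passed over all genes, and 3 were higher adjusted over the list alone (median 1.02, adjusted p = 0.000833, and adjusted p = 0.625 with an estimated correlation). Reg3b, a secreted lectin with a close paralog, so that its single value is uncertain, was at 15600 to 37900 FPKM in 5 mutant libraries, at 802 in the day-9 library of set B and at 1150 to 3800 in control. Tgtp1, an interferon-induced GTPase, was 1.84 higher on the log2 scale (adjusted p = 0.164). Without the day-9 library of set B 10 interferon genes and 8 antimicrobial genes rose, and 0 without any 1 other. Of 15 dissociation stress genes Junb (0.80 ± 0.09, adjusted p = 0.0133) and Ier3 (0.60 ± 0.10, adjusted p = 0.0415), both immediate early genes, rose (median 0.32, adjusted p = 0.00188, and adjusted p = 0.323 with an estimated correlation), so 2 markers of tissue handling moved with the group. The list median on log2(FPKM + 1) differed little: 4.306 to 4.422 in control, 4.289 to 4.39 in 5 mutant libraries and 4.619 in the day-9 library of set B. Leaving out the day-9 library of set B, 4 stress genes rose and 1 fell, against 0 to 2 that rose without any 1 other. The 4 tested endothelial markers were all positive (median 0.46, adjusted p = 0.00692, and adjusted p = 0.323 with an estimated correlation), and none passed over all genes. Without the day-9 library of set B 1 passed, and 3 were higher adjusted over the list alone in that fit.

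**Figure D4:**
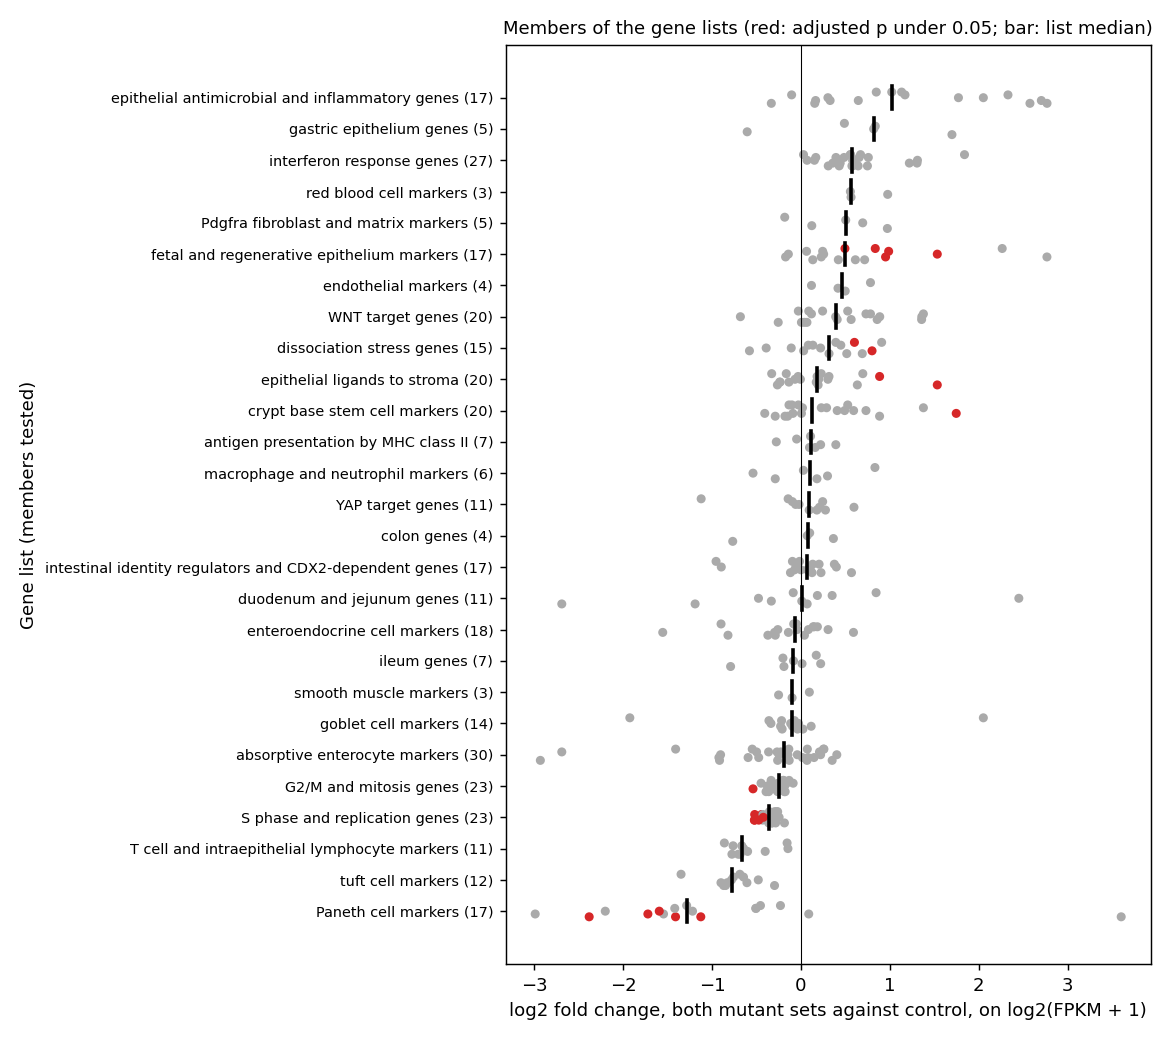
Log2 fold change of both mutant sets against control for each tested member of 27 gene lists, 1 point per gene, red where the gene passed an adjusted p of 0.05 over all genes, with a bar at the list median. The Paneth cell list has the lowest median, −1.28, and the antimicrobial list the highest, 1.02.

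The other lists did not pass in this comparison. They were the goblet (adjusted p = 0.0999), enteroendocrine (0.359) and absorptive enterocyte (0.284) markers, the intestinal identity genes (0.462), YAP targets (0.515), gastric genes (0.158), MHC class II genes (0.729), fibroblast (0.222), smooth muscle (0.545), macrophage (0.482) and red blood cell (0.227) markers, and the duodenal (0.851), ileal (0.725) and colonic (0.92) genes. Without the day-9 library of set B the enterocyte list passed as lower (median −0.20, adjusted p = 0.0298, and adjusted p = 0.777 with an estimated correlation), with 2 of 30 members lower. Fibroblast markers differed between the mutant libraries: the list median on log2(FPKM + 1) was 0.86 to 0.94 in control, 1.74, 1.93 and 0.82 at days 8, 9 and 10 of set A, and 1.29, 2.07 and 0.88 in set B. Col3a1, a collagen gene, was at most 0.0362 FPKM in control, at 0.842, 1.58 and 0.0825 in set A, and at 0.214, 1.88 and 0.103 in set B.

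Set A against control asks what the libraries titled with the β-catenin allele alone expressed. Rpl34 and Rpl30 fell by 5.38 and 3.68, with their copies as above, and there was a fall of Defa6 (−2.01 ± 0.23, adjusted p = 0.026) and Defa23 (−1.96 ± 0.27, adjusted p = 0.0364). Ghrl, which encodes the hormone ghrelin, fell from 55.4 ± 7.88 to 30.8 ± 3.32 FPKM (−0.82 ± 0.11, adjusted p = 0.0364). Pla2g5, a secreted phospholipase, rose by 1.62, Mboat1, an acyltransferase, by 1.16 and Myl7, a myosin light chain, by 1.03. Bckdhb and Ttk fell by 0.72 and 0.57, and Akr1b8, Ccdc3, Lpcat4 and Junb rose by 1.67, 1.19, 0.94 and 0.79. In limma 26 genes passed, 15 higher and 11 lower, and 2015 had an unadjusted p under 0.05. The count was 124 without set B replicate 2 and between 3 (without set A replicate 2) and 14 without any other library: 7, 11 and 7 without control replicates 1, 2 and 3, then 14 and 8 without set A replicates 1 and 3, and 9 and 12 without set B replicates 1 and 3. With the day as a block it was 16. Of the 14 named genes that passed, 3 passed whichever library was left out: Pla2g5, Rpl34 and Rpl30. No member of the Paneth cell list passed over all genes, and 12 of 17 were lower adjusted over the list alone (median −1.56, adjusted p = 9.47e-10, and adjusted p = 0.427 with an estimated correlation). No fetal marker passed over all genes, and 7 of 17 were higher adjusted over the list alone (median 0.41, adjusted p = 0.000116, and adjusted p = 0.323 with an estimated correlation).

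Set B against control asks the same of the libraries titled with both alleles. It showed rises of Igfbp4, an IGF-binding protein, from 23.7 ± 4.8 to 109 ± 39 FPKM (2.11 ± 0.27, adjusted p = 0.0208), Akr1b8 (2.10 ± 0.21), Sprr2a3 (2.07 ± 0.24) and Gkn3, a gastrokine gene, from 16.7 ± 1.41 to 57.9 ± 10.6 (1.72 ± 0.18, adjusted p = 0.00856). Ccdc3 rose from 3.45 ± 0.585 to 11.6 ± 1.6 FPKM and Pla2g5 by 1.38. Defa29 fell by 1.91, Defa6 by 1.37, Cmah, a sialic acid hydroxylase, by 1.17 and Adarb2 by 1.05, and Rpl34 and Rpl30 fell by 5.67 and 3.95. Krt7, Plaur and Marcksl1 of the fetal list rose by 0.61, 0.91 and 1.15, Junb and Ier3 by 0.81 and 0.70, and Ttk fell by 0.51. In limma 76 genes passed, 47 higher and 29 lower, and 1997 had an unadjusted p under 0.05. Without set B replicate 2 the count was 477, and it was 25, 23 and 21 without control replicates 1, 2 and 3, 69, 52 and 58 without set A replicates 1, 2 and 3, and 23 and 18 without set B replicates 1 and 3. A fit to set B and control alone gave 33. Of the 19 named genes that passed, Akr1b8, Ccdc3, Pla2g5, Rpl34 and Rpl30 passed whichever library was left out. On the WNT target list none passed over all genes and 9 were higher and 2 lower adjusted over the list alone (median 0.49, adjusted p = 0.000206, and adjusted p = 0.587 with an estimated correlation).

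The sets share their controls, so part of any overlap may come from those libraries. Of 15 genes higher in set A and 47 in set B, 13 were the same, and of 11 and 29 lower, 9 were the same. Over all tested genes the fold changes correlated at 0.852, and at 0.502 in 100 simulations of unchanged sets against shared controls. The covariances were 0.11 and 0.0215. With separate controls, 1 for one set and the others for the other set, a check added after the result was seen, the 6 assignments gave correlations of 0.539 to 0.657 and covariances of 0.0848 to 0.0975. These correlations are across genes, which are not independent replicates.

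Comparing the mutant sets with each other asks what the Cdx2 allele changed. Cdx2 itself is described above, and no list member passed. No gene passed in limma (smallest adjusted p = 0.109), and 376 had an unadjusted p under 0.05 where chance gives 605. Without set B replicate 1 a single gene, the microRNA gene Mir7036b, passed. The genes with the smallest p all failed the correction. They were 2610528A11Rik (set A 3.68 ± 0.159, set B 1.49 ± 0.156 FPKM), Ghrl (30.8 ± 3.32 and 58.1 ± 1.67, adjusted p = 0.19), Myl7 (34.5 ± 3.03 and 15.8 ± 3.01, adjusted p = 0.218), Mir140, which was listed at 0 in the 3 libraries of set B and at 1.58 to 3.51 in set A, and Tst (16.9 ± 1.9 and 27.5 ± 2.91, adjusted p = 0.263). As 1 FPKM is 16.8 to 19.1 fragments per kilobase, short microRNA entries such as Mir140 and Mir7036b rest on few fragments at low values. The fixed genes Axin2, Lgr5, Olfm4, Ly6a, Clu and Lyz1 differed by 0.22, 0.63, 0.24, 0.30, 1.36 and 0.37, each with an adjusted p of 1. The differences of Axin2 and Ly6a turned sign in some fits that left out a library, as given in the section on processing. Several lists passed at the preset correlation with no member past the threshold over all genes, and none passed with an estimated one. Interferon genes, for example, were higher in set B (median 0.37, adjusted p = 1.12e-07, and adjusted p = 0.622 with an estimated correlation), and without the day-9 library of set B the median was 0.74 (adjusted p = 1.27e-23, and adjusted p = 0.417 with an estimated correlation), with 14 of 27 higher adjusted over the list alone. WNT target genes were higher as well (median 0.23, adjusted p = 1.86e-05, and adjusted p = 0.553 with an estimated correlation), but not without the day-9 library of set B (adjusted p = 0.123). Red blood cell genes were lower (median −1.54, adjusted p = 0.000131, and adjusted p = 0.323 with an estimated correlation), with Hbb-bs at 10.5, 7.42 and 2.49 FPKM in set A and 0.587, 1.91 and 0.249 in set B. The list median on log2(FPKM + 1) was 0.938 to 1.585 in control, 3.518, 3.074 and 1.703 in set A, and 1.341, 2.305 and 0.529 in set B. All of set A thus lay above the control range, while set B lay inside it at day 8, above it at day 9 and below it at day 10.

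No gene followed the day across the 9 libraries in limma. The smallest adjusted p was 0.336, for Snord8 (log2 −0.67 per day), and Per1, a clock gene, came next (0.70 per day, adjusted p = 0.673). An unadjusted p under 0.05 was found for 390 genes, where chance gives 605. The slope was common to the groups, and neither slopes that differ between groups nor a day effect off a straight line was tested here.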

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

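The tests on ribosomal copies, depth, sex, Paneth cell genes and the WNT target list of the day-9 library of set B were chosen only after the result was seen, while the test of a wrong label by the genes called without that library was planned.

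Among the 6 mutant libraries, 61 named genes, list medians and Xist were tested for a library far from the others, with the gap to the nearest library given as a share of the range. Chance flags about 1 in 20, or about 3 here, and 11 stood out. The day-9 library of set A was lowest for Lyz1 (0.822), Ang4 (0.639), Defa24 (0.638), Cdc6 (0.749) and the intestinal identity list (0.764), and highest for Rpl34 (0.732). The day-9 library of set B was highest for the YAP target list (0.679), the endothelial list (0.652), the dissociation stress list (0.692) and the duodenal and jejunal list (0.775), and lowest for Xist (0.902). Every library of set A lay on one side of the control mean and every library of set B on the other for Ghrl (set B minus set A 0.90 on the log2 scale) and 2610528A11Rik (−0.91), a difference that failed the correction (adjusted p = 0.19 and 0.109), so it is not established.

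Rpl34 and Rpl30 were far lower in every mutant library. Reads assigned to a near-identical copy may account for the falls, since the summed FPKM of Rpl34 and Rpl34-ps1 differed by 0.194 on the log2 scale and that of Rpl30 and Gm12191 by 0.0841. In control replicate 2 Rpl34-ps1 made up 52.3% of the sum, against 0.217 and 0.425% in the other controls and at least 97.2% in the mutants. An inherited sequence variant that decides which copy the reads match could give such levels. Gm12191 made up 49.9 to 51.6% in every control and at least 96.2% in the mutants, with no library at a low share. Whether reads that match both copies were split evenly was not tested for this pair. A change in transcription of the pseudogenes stays open, as reads were not examined. If inherited, such a difference runs along the contrast of mutants with control. For any gene in that contrast it cannot be told apart from the mutant allele.

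The day-9 library of mutant set B lay near the controls on the first principal component. The planned test of a control library under a mutant label does not decide: of the 994 genes called without it, it lay nearer to the other mutants than to control for 44.6% (34.1% of the higher and 57.9% of the lower genes), and the bound of 25% set for a control was too low, since on as many genes the left-out controls gave 39.5, 19.2 and 20.6% and the other mutants 73.2 to 92.5%. A wrong label is argued against by the WNT target list, whose median lay 1.18 above the control mean on the log2 scale (4.75, against 3.45 to 3.64 in control and 3.71 to 4.19 in the other mutants). Its shares of Rpl34-ps1 (98.6%) and Gm12191 (96.8%) were also within the range of the mutants, against at most 52.3% and 51.6% in control. Depth is argued against, since its effective size, 18.8 in units of 1e6 fragments, lay within the range of the others (16.8 to 19.1). It is the 1 library with Y-linked expression, so sex and any other difference of that library cannot be told apart.

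Most Paneth cell genes were lower in the mutants, though the list did not pass with an estimated correlation. Its median on log2(FPKM + 1) overlapped between groups: 10.7, 9.592 and 10.73 in control, 9.641, 8.336 and 9.958 in set A, and 9.899, 9.456 and 10.16 in set B. Under equal-total scaling the median log2 fold change of the list was −1.24, and without the day-9 library of set B it was −1.23. The summed FPKM of all 27 Defa genes had a log2 fold change of −1.25, with every mutant library below every control library. Equal totals moved the median gene by only 0.0351, so the choice between these scalings is too small to make such a fall. No other scaling was tried, so scaling in general was not tested. Reads moving between defensin genes and the day-9 library of set B are each argued against. The 11 members that are not defensins had a median of −1.28, with 9 negative. A lower share of Paneth cells and a lower output per cell both remain open as hypotheses, as bulk RNA does not separate them. An inherited sequence difference between control and mutants, raised above for Rpl34, was not tested as a cause here or for the other genes that differed.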

How the results depend on the processing

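Equal-total scaling, the stricter filter, library weights, the day trend with pseudocount 0.1, separate controls for sets A and B and the list tests without set B replicate 2 were chosen only after the result was seen. For both sets against control (140 genes), 80 passed with no filter on low values (19704 genes tested), 1438 with library weights, 43 with an absolute log2 fold change of at least 1, and 17 to 994 with a library left out; 97 passed with the day as a block, 68 of them among the 140. For set A (26), 16 passed with the day as a block, 44 with library weights, 16 with the fold change limit and 3 to 124 with a library left out. For set B (76), 2035 passed with library weights, 33 in a fit to the compared groups, 35 with the fold change limit and 18 to 477 with a library left out. Between the sets (0), 2 passed with pseudocount 0.1 (2610528A11Rik and Mir140), 3 with library weights (2610528A11Rik, Myl7 and Pcsk6) and 0 to 1 with a library left out. Of the list tests (45 of 108), 0 passed in camera with a correlation estimated per list (smallest adjusted p = 0.323), 47 with the day as a block, 51 with equal totals and 51 without set B replicate 2 (39 of the latter among the 45). Without set B replicate 2, for both sets against control, fry passed for the S phase (adjusted p = 0.0242), fetal (0.0239) and antimicrobial (0.0242) lists. It also passed for the interferon (0.044), endothelial (0.0242) and dissociation stress (0.0242) lists. The other lists did not pass by fry, such as the Paneth cell (adjusted p = 0.0917), G2/M (0.0804), tuft cell (0.105) and WNT target (0.248) lists. The estimation of library weights stopped before it converged. Equal totals moved the median gene by at most 0.0542 and turned the balance for both sets to 133 higher and 36 lower. Between the sets the difference of Axin2 ran from −0.037 (without set B replicate 2) to 0.39 with a library left out, and that of Ly6a from −0.58 (without set B replicate 3) to 1.81, with −0.09 without set A replicate 2 and −0.33 without set B replicate 1. The cause was not tested. No day trend passed under any alternative run. Of 9 same-day pairs of libraries 2 correlated above 0.1, both between the mutant sets (0.398 at day 9 and 0.615 at day 10, with −0.0178 at day 8). Pairs of different days passed 0.1 too, such as set A replicate 1 with set B replicate 2 (0.294) and control replicate 2 with set B replicate 1 (0.262). Only 1 library correlated best with its own day in both other groups, so a shared day effect is not established. With the day as a block 0 genes passed between the mutant sets. The planned count-based alternatives (edgeR with other scalings and filters, DESeq2 and voom) were not run, as the values are not counts.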

Other observations

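No test in this part was chosen after the result was seen, as the counts of other splits were planned, and the gene values come without a test of their own.

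Some genes chosen after their values were seen differed widely among the mutant libraries. Lct, the lactase gene, was at 48.1 to 138 FPKM in control, at 2.58 to 21.1 in 5 mutant libraries and at 98.1 in the day-9 library of set B. Cyp3a11, a cytochrome of enterocytes, was at 58.9 to 164 FPKM in control, at 0.953 to 39.4 in the same 5 libraries and at 230 in that library. Neither passed between both sets and control (adjusted p = 0.215 and 0.312). The enterocyte list median on log2(FPKM + 1) was 7.62 in that library, 6.53 to 7.39 in the other mutants and 6.67 to 7.81 in control. Trpm5, an ion channel of tuft cells, was at 5.28 to 7.97 FPKM in control and at 1.33 and 1.63 in the day-10 libraries of sets A and B, and at 6.32 in the day-9 library of set B.

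The same library had the highest values of several WNT targets. Nkd1, a feedback inhibitor, was at 27.5 FPKM there, at 1.4 to 10.9 in the other mutants and at 1.88 to 2.26 in control, and Tnfrsf19 was at 23.4, 3 to 12 and 2.26 to 3.33. Fstl1, a secreted glycoprotein gene on the stem cell list, was at 8.24 there, at 0.0973 to 1.22 in the other mutants and at 0.128 to 0.264 in control. Lcn2, which encodes an antimicrobial lipocalin, was at 4 FPKM there, against 5.16 to 8.22 in control, and at 20.2 to 135 in the other mutants.

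Other splits of the libraries were counted for each comparison. For both sets against control 2 of 100 splits (drawn from 840, the real one included) gave at least the real 140 genes, a share under the planned 0.05. A wrong split gave more genes than the real one, however. The count thus answers to any structure of the samples and does not by itself exclude chance. The highest other split, with 413 genes, puts the day-9 library of set B among the controls, control replicate 1 in set A and set A replicate 3 in set B, which points to a structure of the samples. For set A 1 of 10 splits reached the real 26 genes (highest other 2), for set B 1 of 10 reached the real 76 (highest other 2), and between the sets 10 of 10 reached the real 0 (highest other 127, which exchanges set A replicate 3 and set B replicate 2). In limma 376 genes between the sets had an unadjusted p under 0.05. These 10 splits are too few for a share under 0.05.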
